A study of Tachysurus ussuriensis with 12 samples.

How the data were processed

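Transcript abundance was measured by RNA sequencing of total RNA from gill and kidney of the Ussuri catfish, sampled at 0 h and 24 h of acute salinity stress, in 12 libraries that form 4 groups of 3. The groups were taken from the tissue and time in the sample labels. The labels give neither the salinity nor whether the 3 samples of a group came from separate fish, so the p-values measure the spread between these samples, which may in part be technical. RNA was extracted with TRIzol, per the labels' protocols, and the submitters' processing notes name Trimmomatic, a read trimmer, without a version. The assembly settings, the aligner and the counting program are not given in the sources used here.

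The authors deposited FPKM values (fragments scaled for transcript length and for the number of mapped fragments of the library) for 84875 transcripts, 1 column per library, per the file headers. The transcript IDs have the form that the assembler Trinity writes, followed by a number from 1 to 4 whose meaning is not given in the sources used here. The rows are assembled transcripts, so several of them can be pieces of 1 gene. The files do not pair the IDs with gene names, and no reference genome or annotation was used here. For that reason the 26 gene lists and 16 cell type marker sets that had been fixed for these tissues could not be matched to any transcript and were not tested. Because FPKM values are not counts, no count model was fitted, and read totals per library are unknown. Sequencing depth of the libraries relative to each other was recovered from the steps between low values of 11963 transcripts that were listed at 0 in at least 4 libraries. It ran from 0.861 in kidney 24 h replicate 2 to 1.12 in kidney 24 h replicate 1, and the 66 pairs of libraries gave a median residual of 0.0059 on the log2 scale. The largest residual of a pair was 0.0302. On 40000 simulated transcripts the method erred by at most 0.04%, but these held whole reads only, so that error need not hold for the deposited values. With relative depths this close, depth gave similar precision in all 12 libraries, while the absolute precision of a single FPKM value is unknown.

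Tests were made with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a mean-variance trend) on log2(FPKM + 1), so fold changes are on that scale and understate the change of low transcripts. Transcripts with an FPKM of 1 or more in at least 3 of the 12 libraries were tested, which kept 75716 (89.2%) and left out 9159. A single model with 4 group means was fitted to all 12 libraries, which leaves 8 residual degrees of freedom and gives all comparisons a shared estimate of the spread. A transcript was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, with no minimum fold change. The comparisons were 24 h against 0 h in each tissue, the difference between those changes (kidney minus gill), and gill against kidney at each time. The tests, the samples in them and most alternatives were fixed before the data were examined. The named transcripts are those with the largest fitted rise and the largest fitted fall among the called transcripts of each tissue whose 2 groups do not overlap in FPKM. The fixed rule allowed more for each comparison; because the IDs have no gene names, only 2 transcripts chosen for a rise and 2 chosen for a fall are named in all.

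The tests were checked on simulated data made from the means and spread of the 75716 tested transcripts, with 100 transcripts changed by each of 2 sizes. The changed transcripts were drawn only from those above a minimum mean level, so the shares recovered do not cover the lowest transcripts. Of changes of 1 on the log2 scale, 17% were recovered for gill, 13% for kidney, 1% for the difference between the tissues' changes, 16% for the tissues at 0 h and 16% for the tissues at 24 h. Of changes of 2 on the log2 scale, 56%, 58%, 26%, 60% and 61% were recovered in the same order. False calls numbered 3, 4, 0, 5 and 9. The tests thus missed many of the simulated changes, most of all in the difference between the tissues' changes. Few transcripts were changed in the simulation, so the adjusted threshold was stricter than between tissues in the data, where 22199 and 23262 were called. Each transcript's spread was the same in all simulated libraries, unlike in the data. The shares recovered and the false calls need not hold for the data, least of all between tissues.

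Tissue-preferring sets were defined as transcripts called in the average of both times between gill and kidney with a difference of at least 1 on the log2 scale, and their mean level was compared between times with an exact permutation test, whose smallest two-sided p with 3 against 3 libraries is 0.1. These sets were chosen on the same libraries in which they were compared. The replicate numbers in the sample titles were checked as a pairing. Deviations from the group means of same-numbered gill and kidney libraries of 24 h correlated at 0.137, 0.111 and 0.109, all above 0.1, so a fit with the number as a block was set beside that comparison. No other pair of groups had 3 correlations above 0.1. The number that ends each library name, which differs from the title number in some samples, was tried as a block as well.

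Alternatives were another pseudocount, other filters on low FPKM, median-ratio, equal-total and quantile scaling, other variance models, fits to only the 2 groups compared, a minimum fold of 2, blocks by replicate number, and leaving out each library in turn. Chosen after the data were seen were library weights, equal totals set to the mean total of the libraries (in place of a larger fixed total, so that the pseudocount keeps its relative size), and a term for the 3 libraries in which the transcripts of each ID number stood highest, with and without kidney 0 h replicate 2. For that term each library was assigned to the ID number whose transcripts stood highest in it relative to the other libraries of its tissue. Relative depth and figures were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.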

Results

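The series compared transcript levels of gill and kidney in the Ussuri catfish (Tachysurus ussuriensis, also placed in Pseudobagrus), a freshwater bagrid catfish, at 0 h and 24 h of acute salinity stress. Gill and kidney are the main organs of ion and water balance in freshwater fish. Each of the 4 groups held 3 libraries. The labels name no group of 24 h without salinity stress, so changes over time cannot be assigned to salinity. FPKM summed to between 631998 and 714003 per library, and between 73001 and 79053 of the 84875 assembled transcripts had a value above 0. Within groups the libraries correlated at r = 0.897 to 0.913 over tested transcripts, leaving out kidney 0 h replicate 2, and libraries of different tissues correlated at 0.566 to 0.662. The first principal component (57.0% of variance) separated gill from kidney and the third (7.04%) parted 0 h from 24 h within gill. Kidney 0 h replicate 2 stood apart: it correlated at 0.816 to 0.838 with the other 5 kidney libraries, lay alone on the second component (9.16%), and had a median FPKM of 1.26 against 1.85 to 2.22 in the other 11 libraries. Its relative depth of 1.03 was within the range of the others.

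**Figure D1:**
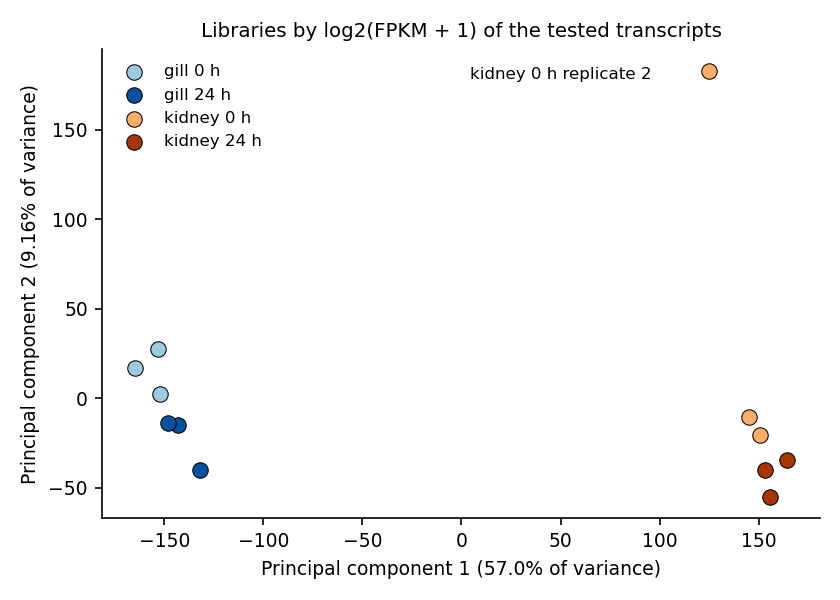
Each point is a library, placed by its scores on the first (horizontal) and second (vertical) principal components of log2(FPKM + 1) of the tested transcripts, coloured by tissue and time. Gill libraries lie left of 0 and kidney libraries right of 0, and kidney 0 h replicate 2 has a score of 183 on the second component.

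Gill and kidney differed at 0 h in 22199 transcripts, of which 13093 were higher in gill and 9106 higher in kidney, with a median absolute difference of 1.41 on the log2 scale among those called. At 24 h they differed in 23262 transcripts, 11832 higher in gill and 11430 higher in kidney, with a median of 1.40. The numbers higher in gill and higher in kidney moved with the setting: at 0 h they were 12144 and 11624 with quantile normalization, 13359 and 10069 with median-ratio scaling, and 12881 and 12037 without kidney 0 h replicate 2. At 24 h more were higher in kidney with equal totals (11154 in gill, 12553 in kidney) and without kidney 0 h replicate 2 (13411 and 14520), and more in gill with median-ratio scaling (12919 and 10380). The differences were largely shared between times: 16469 transcripts differed in the same direction at both, 44 in opposite directions, and across all tested transcripts the differences at 0 h and 24 h correlated at r = 0.851 (Spearman rho = 0.767; transcripts are not independent replicates, and no library is shared between the times). Of the transcripts found in all 6 gill libraries at an FPKM of 1 or more, 780 were below 0.1 in all 6 kidney libraries, and 487 of these were listed at 0 there. In the other direction 387 transcripts were at 1 or more in all 6 kidney libraries and below 0.1 in all 6 gill libraries, 195 of them listed at 0. At or above an FPKM of 1 in all 12 libraries were 28316 transcripts.

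The gill and kidney libraries did not overlap in FPKM for 39.1% of tested transcripts at 0 h and 48.5% at 24 h, where chance gives 10%. The share of called transcripts higher in gill at 0 h was 42.3% among transcripts whose ID ends in 1, 93.3% for 2, 12% for 3 and 72.9% for 4, and at 24 h the shares were 29.4%, 88.9%, 11.4% and 71.9%. With a term for the 3 libraries in which each number's transcripts stood highest, 18607 transcripts were called at 0 h and 20976 at 24 h.

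In gill, 642 transcripts changed between 0 h and 24 h, 314 rising and 328 falling, or 0.848% of those tested. Of these, 597 changed at least 2-fold, and the median absolute change was 1.60 on the log2 scale. The largest rise was that of TRINITY_DN20352_c0_g1_i1_3, from 13.7 ± 4.66 FPKM at 0 h to 308 ± 70.2 at 24 h (SD, n = 3 each), a log2 fold change of 4.42 (SE 0.26; limma adjusted p = 8.51e-05). The largest fall was that of TRINITY_DN22648_c0_g1_i5_2, from 205 ± 131 to 4.48 ± 4.07 FPKM (SD, n = 3 each), a log2 fold change of -5.37 (SE 0.77; limma adjusted p = 0.0119). In kidney the second transcript had 7.44 ± 2.87 FPKM at 0 h and 7.09 ± 4.98 at 24 h (SD, n = 3 each; limma adjusted p = 0.978), and the difference between its changes in the tissues was not called (5.19, SE 1.09; limma adjusted p = 0.164). Its gill call was lost with a pseudocount of 0.1 (limma adjusted p = 0.0528), in a fit to the 2 gill groups alone (0.0999) and without gill 0 h replicate 3 (0.0582), while its adjusted p over all alternatives ranged from 0.00105 to 0.0999.

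Gill libraries of 0 h and 24 h did not overlap in FPKM for 21.2% of tested transcripts, against 10% by chance, and for all 642 called transcripts. The direction of the gill calls went with the number that ends the transcript ID. Of called transcripts, 120 of those ending in 1 rose and 29 fell, 91 rose and 200 fell for 2, 29 rose and 28 fell for 3, and 74 rose and 71 fell for 4. The term for the libraries of each number left 463 called transcripts (200 rising, 263 falling), 411 of them among the 642. The count fell to 219 with a pseudocount of 0.1 and 250 with only the gill groups fitted, and to 218 and 164 without gill 0 h replicates 1 and 3, 214, 163 and 312 without gill 24 h replicates 1, 2 and 3, and 391, 402 and 418 without kidney 24 h replicates 1, 2 and 3. It rose to 1027 (311 rising, 716 falling) without gill 0 h replicate 2, and to 1648 (928 rising, 720 falling), all 642 among them, without kidney 0 h replicate 2. Library weights gave 2208 (1157 rising, 1051 falling). The lowest counts were 32 with a block by replicate number and 5 with a block by library name number. These blocks join same-numbered gill libraries of 0 h and 24 h, whose deviations from the group means correlated at only -0.0249 to 0.0125.

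In kidney, 624 transcripts changed between 0 h and 24 h, 472 rising and 152 falling. Of these, 566 changed at least 2-fold, and the median absolute change was 1.56 on the log2 scale. TRINITY_DN35749_c0_g1_i1_4 rose the most, from 2.90 ± 2.00 to 75.5 ± 36.2 FPKM (SD, n = 3 each), a log2 fold change of 4.37 (SE 0.43; limma adjusted p = 0.00177), and was at most 0.111 FPKM in all 6 gill libraries. TRINITY_DN27698_c0_g1_i4_1 fell the most, from 159 ± 130 to 6.03 ± 2.42 FPKM (SD, n = 3 each), a log2 fold change of -4.28 (SE 0.56; limma adjusted p = 0.00728). In gill its levels were 422 ± 209 and 152 ± 78.5 FPKM (SD, n = 3 each), with a log2 fold change of -1.49 that was not called (limma adjusted p = 0.303), and the difference between the tissues' changes was not called either (-2.79, SE 0.79; limma adjusted p = 0.296). In a fit to the 2 kidney groups alone both kidney calls were lost (limma adjusted p = 0.175 for the first and 0.19 for the second), within ranges over all alternatives of 0.00107 to 0.205 and 0.00527 to 0.205.

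The excess of rising transcripts in kidney depended on the scaling. The median change of all tested transcripts was 0.10 on the log2 scale as deposited and -0.01 with median-ratio scaling, under which 375 transcripts rose and 376 fell. With quantile normalization 421 rose and 290 fell, and with equal totals, which kept the excess, 435 rose and 161 fell (median change 0.11). The excess also went with the ID number: of called transcripts ending in 1, 279 rose and 21 fell, whereas 53 rose and 29 fell for 2, 85 rose and 59 fell for 3, and 55 rose and 43 fell for 4. The term for the libraries of each number left 181 called transcripts (130 rising, 51 falling), 166 of them among the 624. Kidney libraries of 0 h and 24 h did not overlap for 15.7% of tested transcripts, against 10% by chance. The count fell to 408 with a pseudocount of 0.1 and to 13 (3 rising, 10 falling) in a fit to the kidney groups alone; it was 331 and 405 without gill 0 h replicates 1 and 3, 371, 377 and 352 without gill 24 h replicates 1, 2 and 3, and 302, 126 and 262 without kidney 24 h replicates 1, 2 and 3. Without kidney 0 h replicate 2 it rose to 2073 (1265 rising, 808 falling), 574 of the 624 among them. With library weights it was 1486 (863 rising, 623 falling). Blocks by replicate number and by library name number each left 0. These blocks join same-numbered kidney libraries of 0 h and 24 h, whose deviations from the group means correlated at only -0.0493 to 0.0797.

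**Figure D2:**
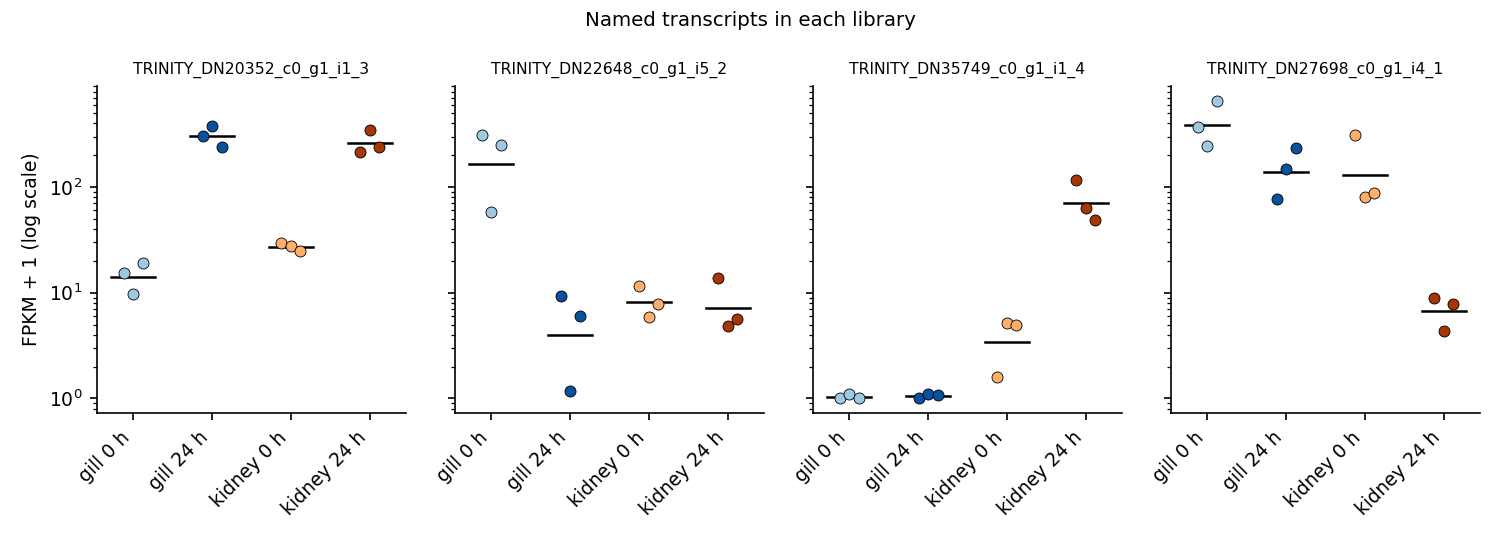
FPKM plus 1 on a log scale for the 4 named transcripts in each library, by tissue and time, with a bar at the mean of the log2 values of each group of 3. TRINITY_DN20352_c0_g1_i1_3 was higher at 24 h in both tissues, and TRINITY_DN35749_c0_g1_i1_4 stayed at or below 0.111 FPKM in gill.

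Gill and kidney shared part of the 24 h change. Of the called transcripts, 40 rose in both tissues, where independent lists of these sizes would share 1.96, and 25 fell in both, where 0.659 would be shared. None rose in 1 tissue and fell in the other, where 2.05 and 0.630 would be shared in the respective directions. TRINITY_DN20352_c0_g1_i1_3, the transcript with the largest rise in gill, also rose in kidney, from 26.4 ± 2.43 to 266 ± 69.3 FPKM (SD, n = 3 each), a log2 fold change of 3.25 (SE 0.26; limma adjusted p = 0.00068). Over all alternatives its limma adjusted p ranged from 5.55e-05 to 0.0642 in gill and from 0.000684 to 0.205 in kidney, with both calls lost under a block by library name number and the kidney call also under a block by replicate number (0.0536). Across all tested transcripts the changes of the tissues correlated at r = 0.240 (Spearman rho = 0.214). Same-numbered gill and kidney libraries of 24 h deviated together (correlations 0.137, 0.111 and 0.109), which raises the values to be had with no change: their covariance alone amounts to a correlation of 0.0314, or 0.0432 with the libraries of 0 h included, and the numbers for independent lists leave it out. For these changes a block by replicate number joins the 0 h and 24 h libraries of 1 tissue, so it does not test deviations shared between tissues. With that block limma called 0 transcripts in kidney (9803 unadjusted p-values under 0.05), so none were called in both. Within the 4 ID numbers r ranged from 0.194 to 0.246. With the term for the libraries of each number, 17 transcripts rose in both tissues (0.343 for independent lists), 11 fell in both (0.177) and none moved in opposite directions.

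**Figure D3:**
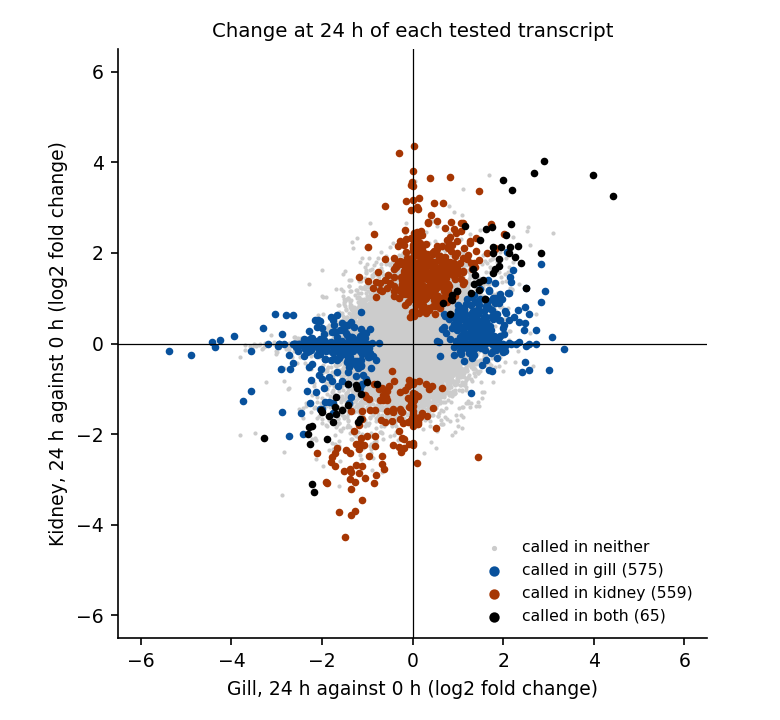
Each point is a tested transcript, placed by its log2 fold change from 0 h to 24 h in gill (horizontal) and in kidney (vertical); colours mark transcripts called in gill, in kidney, in both or in neither. The transcripts called in both tissues lie in the quadrants of a shared rise (40) or a shared fall (25).

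The change over 24 h differed between the tissues in 38 transcripts, with the kidney change above the gill change in 26 and below it in 12. These comprised 13 that fell in gill and were not called in kidney, with a median log2 change in gill of -2.37, and 13 that rose in kidney and were not called in gill, with a median of 3.11 in kidney. A further 8 rose in gill and were not called in kidney, and 4 fell in kidney and were not called in gill. TRINITY_DN35749_c0_g1_i1_4 was among those that rose in kidney: its kidney change exceeded its gill change by 4.34 on the log2 scale (SE 0.60; limma adjusted p = 0.0443), and with the term for the libraries of its ID number the adjusted p was 0.059. Median-ratio scaling gave 43 transcripts, 23 above and 20 below, and quantile normalization 49, 29 above and 20 below; each held 33 of the 38. Of the 38, 13 ended in 1 (11 above, 2 below), 13 in 2 (10 above, 3 below), 4 in 3 (1 above, 3 below) and 8 in 4 (4 above, 4 below).

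The count of these transcripts moved with single settings and libraries. It was 9 with equal totals (40 when the totals were set to their mean), 1 with a pseudocount of 0.1, 18 with the term for the libraries of each number, 452 (404 above, 48 below) without gill 0 h replicate 2 and 69 without kidney 0 h replicate 2, while leaving out any of the other 10 libraries gave 0 to 12. With the replicate number as a block, 0 were called by limma. Unadjusted limma p-values under 0.05 numbered 6606 without the block and 6422 with it.

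**Figure D4:**
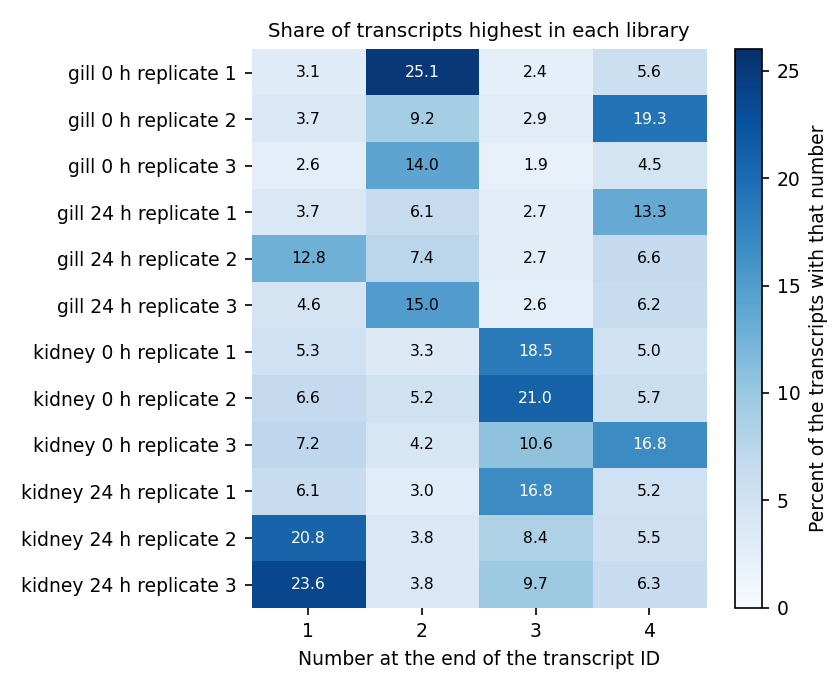
Each cell gives the percentage of all listed transcripts with the ID number on the horizontal axis that had their highest FPKM in the library on the vertical axis; darker cells are higher. For each number 3 libraries have the highest percentages, such as gill 24 h replicate 2 and kidney 24 h replicates 2 and 3 for number 1.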

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

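The test of the difference between the tissues' changes called 38 transcripts, 26 with the kidney change above the gill change and 12 below, which is a difference between groups under the same contrast. The term for the libraries that lead an ID number and equal totals set to their mean were chosen after the result was seen; leaving out each library was planned, but the bounds for reading it without kidney 0 h replicate 2 were set afterwards. Of 100 splits drawn from the 200 possible splits of the times within each tissue, 2 gave as many transcripts, the real split included. The next highest gave 34 and 33. Most splits mix libraries of 0 h and 24 h, so time changes enter their spread and lower their counts. The splits therefore cannot decide whether chance gives 38 where the tissues change alike. A block by replicate number joins same-numbered gill and kidney libraries of each time, a pairing that the labels do not give. With it 0 transcripts were called (6422 unadjusted limma p-values under 0.05). The other of the 2 splits gave 1395. It kept the gill libraries at their times and exchanged the kidney times, so that it tested the sum of the tissues' changes. It points to the shared 24 h change as a structure of the samples.

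The tables argue against kidney 0 h replicate 2 alone as the cause of the 38, since 69 transcripts were called without it, 32 of the 38 among them. The term for the libraries that lead an ID number cannot decide whether those libraries caused the differences. No group had all 3 libraries lead the same number, and the median term over all tested transcripts was 0.15 on the log2 scale. A term of that size moves differences this large only a little, though the term was fitted to each transcript and can be larger in single ones. With it the median ratio of the 38 differences to those without it was 1.00, and all 38 kept their sign. The median absolute difference was 2.58 (median SE 0.346) against 2.61 (median SE 0.334). The term left 18 calls, 13 of them among the 38; the fitted differences stayed, while their SE rose slightly and the term spent 1 residual degree of freedom. The tables argue against scaling between libraries as the cause. Median-ratio scaling gave 43 and quantile normalization 49, each with 33 of the 38. Equal totals above those deposited left 9, but these also shrink the pseudocount relative to the values. Equal totals set to their mean gave 40, with all 38 among them. A difference between gill and kidney in their response to salinity, which the design names, stays open, and leaving out single libraries gave 0 to 452 transcripts. Without a group of 24 h that lacked salinity stress, such a response cannot be told apart from other changes over 24 h.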

How the results depend on the processing

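Library weights, equal totals set to their mean, the term for the libraries that lead an ID number and the set levels were chosen after the data were seen; the other alternatives were planned. The counts between gill and kidney stayed within 1.5 times under all alternatives but 1, and without single libraries ranged from 18185 to 24918 at 0 h and from 19010 to 27931 at 24 h; the exception was a block by library name number at 24 h (12617). The correlation of the tissues' changes stayed between 0.197 and 0.245. Without single libraries the counts over time ranged from 163 to 1648 in gill, from 126 to 2073 in kidney and from 0 to 452 for the difference between them; fewer samples and, for kidney 0 h replicate 2, a spread of 0.555 against at most 0.420 in other libraries enter these. The difference fell to 0 without gill 24 h replicate 1 or 3, kidney 0 h replicate 3 or kidney 24 h replicate 2, with 5528, 5966, 7199 and 5347 unadjusted limma p-values under 0.05. With a pseudocount of 0.1 the 3 counts were 219, 408 and 1, and with equal totals the difference had 9. Fits to only the groups compared gave 250 in gill and 13 in kidney. Library weights gave 2208, 1486 and 106. The term gave 181 in kidney and 18 for the difference, and without kidney 0 h replicate 2 as well it gave 1159 in gill and 1153 in kidney. Beyond the fewer samples or degrees of freedom, the cause was not tested.

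The replicate block changed no call count between gill and kidney by over 1.5 times: 20453 at 0 h and 21484 at 24 h. Same-numbered libraries of 24 h deviated together, but the labels do not say that the numbers pair samples. The title numbers gave the highest mean correlation of 6 matchings at 24 h, but not at 0 h. With the term for the ID numbers the 3 correlations of 24 h were 0.0005, 0.0062 and 0.152. Over time the samples share only a number: same-numbered libraries of 0 h and 24 h deviated together at -0.0249 to 0.0125 in gill and -0.0493 to 0.0797 in kidney, and not every library correlated best with its own number. The block left 32 transcripts in gill, 0 in kidney and 0 for the difference, on 4 residual degrees of freedom. Kidney and the difference had 9803 and 6422 unadjusted limma p-values under 0.05. For the difference the block joins same-numbered gill and kidney libraries of each time, whose deviations at 0 h correlated at -0.0085 to 0.0915. The block by library name number left 5, 0 and 0 (9191 and 5187 unadjusted for the latter pair).

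Of 200 alternative values of the 8 fold changes of named transcripts, 185 kept their direction and side of the threshold. With the replicate block the kidney calls of TRINITY_DN20352_c0_g1_i1_3, TRINITY_DN35749_c0_g1_i1_4 and TRINITY_DN27698_c0_g1_i4_1 were lost (limma adjusted p = 0.0536, 0.0606 and 0.0536). The change of TRINITY_DN22648_c0_g1_i5_2 in kidney, not called, ranged from -0.64 to 0.12 without single libraries; it reversed to 0.08 without kidney 0 h replicate 1, 0.12 without kidney 24 h replicate 2 and 0.0072 without kidney 24 h replicate 3. The mean level of kidney-preferring transcripts in kidney reversed to -0.026 without kidney 0 h replicate 2. No gene list test was run because the files do not pair transcripts with names. Read totals are unknown, so depth sets no stated limit on single low values.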

Other observations

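Gill-preferring transcripts lay lower, in the mean, in each of the 3 gill libraries of 24 h than in each of those of 0 h. The 10686 gill-preferring transcripts had a mean log2 level of 2.88 ± 0.0551 in gill at 0 h and 2.76 ± 0.0221 at 24 h (SD, n = 3 each), a difference of -0.12 (SE 0.034; exact permutation p = 0.1, the smallest these groups allow). The median over the set was -0.04, with 53.1% of transcripts below 0. With the set defined anew under the other scalings the difference lay between -0.09 and -0.15, but it was not limited to gill: in kidney the set differed by -0.07 with median-ratio scaling (SE 0.019) and -0.09 with quantile normalization (SE 0.0291; exact permutation p = 0.1 for both), and by -0.0036 as deposited (SE 0.0406; p = 0.9). Of the 328 transcripts that fell in gill, 221 were gill-preferring (67.4%, against 14.1% of tested transcripts), as were 127 of the 314 that rose. The difference was not alike across ID numbers: 0.15 for transcripts ending in 1, -0.23 for 2, -0.05 for 3 and -0.03 for 4. The 7929 kidney-preferring transcripts differed by 0.19 in kidney (SE 0.188; exact permutation p = 0.5), and by -0.03 without kidney 0 h replicate 2, in which their mean was 2.27 against 2.79 to 2.89 in the other kidney libraries. These sets were chosen on the same libraries.

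The tests of the ID number were chosen after the pattern was seen, except that by single groups and that of number 1 by abundance. The number that ends each transcript ID went with the libraries in which the transcript was highest: 3 libraries held 57.2% of the highest values of transcripts ending in 1 (gill 24 h replicate 2, kidney 24 h replicates 2 and 3), 54.1% for 2 (gill 0 h replicates 1 and 3, gill 24 h replicate 3), 56.2% for 3 (kidney 0 h replicates 1 and 2, kidney 24 h replicate 1) and 49.4% for 4 (gill 0 h replicate 2, gill 24 h replicate 1, kidney 0 h replicate 3); these libraries were picked for standing high, and tissue enters the shares too. The tables argue against low-abundance transcripts only: from transcripts with a mean FPKM of 10 or more, 9 of 12 libraries led the number they led from the rest (3.66 with libraries permuted within tissue; permutation p = 0.00184), and there number 3 was highest in kidney 0 h in 36.8% against 27.3% of all numbers and number 2 in gill 0 h in 28.5% against 20.5%, although number 1 in kidney 24 h stood 5.36 percentage points above all numbers, between the 5 set in advance as fitting and the 10 set as excluding it. An assembly of one group's reads per number stays open, since the planned test met neither of its bounds and held too few transcripts: 14 of 14 present in gill 0 h alone (100%) ended in 2, 1 of 1 in kidney 0 h alone in 3, the 2 in kidney 24 h alone in 1 and 3, and none were in gill 24 h alone; that 0 of the 4 groups had all 3 libraries lead the same number goes against it but rests on single libraries. An assembly of the pooled reads of 3 libraries per number is a candidate explanation that stays open as well: each number had exactly 3 leading libraries, but random values centred in the same way gave that with probability 0.0551 in 100000 draws. No biological explanation was tested. The changes over time may carry part of this structure: with the term for those libraries the median kidney change of transcripts ending in 1 went from 0.33 to 0.17. The fall in called kidney transcripts from 624 to 181 does not measure that part. No kidney library leads number 2 and its median kidney change stayed at 0.029, yet its kidney calls fell from 82 to 36. The term was fitted for each number on its own and spent 1 residual degree of freedom.

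For kidney 0 h replicate 2 the tests of depth and of gill tissue were chosen after it was seen to stand apart. The tables argue against lower sequencing depth (relative depth 1.03, within 0.861 to 1.12). With median-ratio scaling its residual SD was 0.584, against at most 0.426 in the other 11 libraries, so rescaling did not remove its larger spread. This SD is taken around the library's own mean, so a scale factor enters it only through the pseudocount. The test therefore cannot decide whether scaling by a few abundant transcripts lowered its median FPKM. Its median-ratio factor was 0.783, against 0.932 to 1.13 in the other libraries. Gill tissue carried over stays open, since the values point both ways. The mean log2 level of gill-preferring transcripts was 0.83, below the 0.89 to 0.97 of the other kidney libraries. With median-ratio scaling it was 0.94, within their range of 0.85 to 0.96. Neither level lay above all other kidney libraries, which carried-over gill tissue was predicted to give. However, the mean correlation of the library with gill was 0.650, against 0.601 to 0.637 in the other kidney libraries. Its score on the first principal component, where gill lies below 0, was 125, against 145 to 164 in those libraries. The mean of kidney-preferring transcripts, which enters both of these values, was lower in it as well (2.27 against 2.79 to 2.89). The state of that kidney sample and of its RNA stays open and was not tested.

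Other splits of 3 against 3 libraries number 10 with the real split, too few for a share under 0.05, and in each comparison 1 split, the real one, gave as many transcripts. In gill the real split gave 642 and the highest other 6, and in kidney 624 and 1. Between gill and kidney it gave 22199 and 4 at 0 h, and 23262 and 0 at 24 h. Each other split mixes libraries of the 2 groups compared, so the difference between them enters the spread and lowers the count. The low counts of the other splits therefore do not show what chance would give without such a difference.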
